A study of Mus musculus with 12 samples.

How the data were processed

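Gene expression was measured in 12 samples of sorted stem cells, 3 male mice in each of 4 groups (sham, POL5551 for 14 days, and G-CSF for 2 or 5 days), with 1 array per mouse and no pooling. Per the labels, RNA was isolated with digestion of DNA on the column, and the cDNA was labelled chemically with Cy5 and hybridized to Agilent arrays in a single colour. Per the file headers, the scanner files hold the signal of each spot as a fluorescence intensity on a linear scale, made by Agilent Feature Extraction 11.5.1.1. That program subtracted background, removed spatial trends and put a surrogate value on spots not above background, with no normalization between arrays. The table of values deposited by the authors holds intensity values on a linear scale for 49665 probes. Every column of it has the same median, 1080, and a 75th percentile of 3698 or 3699, as after quantile normalization. The tool and the filter behind that table are not given in the sources used here. Each of its columns has the rank order of 1 scanner file of the same group (rank correlation of at least 0.999998). Within the POL5551 group, and between the 5-day mice 2 and 3, the matching file carries another mouse number. Groups are unaffected, and mouse numbers in the text are those of the scanner files.

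The array has 62976 spots, of which 59305 are not controls, for 56605 probes. Spots marked as outliers by Feature Extraction, 60 to 267 per array, were left out, and no spot was saturated. Values were the log2 of the processed intensity in the deposited scanner files minus the array's 75th percentile over all probes other than controls, and repeated spots of a probe were averaged. A probe was tested if it was well above background on at least 3 of the 12 arrays. Probes were named by RefSeq accession and then by symbol or synonym. Each gene was represented by the tested probe with the highest mean over the 12 arrays, giving 33191 genes. The number includes gene models, clones and intergenic transcripts that have no symbol. No reference genome was used, and coordinates are those of the array design on mm9.

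Groups were compared with limma 3.58.1 in R 4.3.3, using a model of group means over all 12 arrays with 8 residual and 3.23 prior degrees of freedom. The comparisons were each treatment with sham, 5 with 2 days of G-CSF, and POL5551 with 5 days of G-CSF, together with the moderated F test over the 4 groups. Tests were two-sided and adjusted by Benjamini and Hochberg's method over all genes, with a threshold of 0.05. An exact test of 3 against 3 cannot go below a p of 0.1, so the tests rest on the spread pooled by limma. Fold changes of the treatments were also correlated across genes, and their expected correlation under shared controls came from 100 simulations of unchanged groups.

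In all, 29 gene lists were tested with camera at a preset correlation of 0.01 between genes, 17 of pathways and 12 of cell type markers, each with at least 5 measured members, and p was adjusted over the 29 lists of a comparison. The pathway lists were HSC identity, quiescence, S phase, G2/M, the CXCR4 axis with adhesion and niche retention, G-CSF receptor and STAT targets, Toll-like receptor signalling, type I interferon, interferon gamma with MHC class II, early response and dissociation stress, unfolded protein response, p53, MYC, ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, and cholesterol synthesis. The marker lists were primary granule, mature neutrophil, macrophage, erythroid, megakaryocyte, B lymphoid, T and NK, lymphoid priming, mast cell, dendritic, endothelial and stromal with osteoblast genes. Off-tissue genes are olfactory, vomeronasal, taste and keratin-associated genes, with 1554 probes.

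Named genes followed a rule. It took up to 8 called genes per direction in each comparison with sham and up to 5 in the others, ordered by size, with groups that did not overlap, a symbol, and signal well above background on all arrays of at least 1 group. Where no gene was called in a direction, the 3 with the smallest p were named. The rule added 2 members per direction of each list that passed in a comparison, 14 fixed genes, and up to 6 genes called in all 3 comparisons with sham. Of the genes the rule names, 3 are not reported here. The groups, comparisons, tests, lists, naming rule and the first set of other settings were fixed before the data were examined.

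The procedure was tested on simulated data with changes planted in 50 genes per size. Of planted changes of 2 on the log2 scale 26% to 40% were recovered, and of those of 4, 68% to 92%, with 3 to 7 false calls per comparison. Both planted lists were recovered. The noise was drawn independently for each gene, so these simulations do not measure false calls where genes vary together over the arrays.

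The other settings chosen in advance were quantile normalization, normexp background correction (offset 50) with quantile normalization, median scaling, a percentile over bright probes, no filter or a filter for signal on all 12 arrays, the mean of a gene's probes, the authors' values, only the 2 groups compared, array weights, a trended and robust prior, mouse number as a block, slide as a fixed or random block, an estimated correlation or ranks in camera, and leaving out each of the 12 arrays. The off-tissue median as a covariate, leaving out 2 arrays that stood apart, and the block with the mouse numbers of the authors' table were added after the data had been seen. In comparing settings, a change of direction was counted only for results that had passed. The 12 arrays lay on 6 slides. Slide 1 held sham 1 and POL5551 mouse 1. Slide 2 held shams 2 and 3 and POL5551 mouse 2, and slide 3 the 2-day arrays. Slide 5 held POL5551 mouse 3 and 5-day mouse 2, and slides 4 and 6 held 5-day mice 1 and 3. Statmod 1.5.0, the package data.table (version 1.17.8), jsonlite 2.0.0 and matplotlib 3.10.9 were also used.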

Results

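Gene expression was measured in haematopoietic stem cells of male mice. Bone marrow was first enriched for Kit-bearing progenitors, and the cells sorted from it by flow cytometry were lineage-negative, Sca-1 and Kit positive and gated on SLAM family markers, the usual definition of mouse stem cells. There were 4 groups of 3 mice. Sham-operated mice were the controls. POL5551, an antagonist of the chemokine receptor CXCR4, was infused at 100 mg/kg per day for 2 weeks. Granulocyte colony-stimulating factor (G-CSF), the cytokine used to move stem cells from the marrow into the blood, was injected at 100 ug/kg every 12 h, with 4 injections in the 2-day group and 9 in the 5-day group. Each mouse gave 1 single-colour Agilent array, 12 in all, and the number of arrays limits the precision. The 75th percentile of the processed signal ran from 1901 on sham 1 to 6810 on mouse 1 of the 5-day G-CSF group. Between 75.3% and 85.6% of probes were well above background, and no probe was saturated. Levels are log2 signal relative to each array's 75th percentile, with SD over 3 mice, and differences carry the limma standard error. Coordinates are those of the probes on mouse build mm9.

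Genes that blood cells do not use differed between the arrays. Olfactory, vomeronasal, taste and keratin-associated genes are called off-tissue genes from here on, and 1172 of them were tested. The median level over their 1554 probes, whether tested or not, was -2.78 ± 1.02 (SD, n = 3) in sham, -4.59 ± 0.53 after POL5551, -2.57 ± 0.16 after 2 days of G-CSF and -3.69 ± 0.40 after 5 days. Sham 1 had the highest value of the 12 arrays, -1.60, against -3.30 and -3.45 in the other shams. Its rank correlation with its own group across genes was 0.783 and 0.788, while shams 2 and 3 had 0.936 with each other. The first principal component, on which sham 1 and the first POL5551 mouse lay at opposite ends (232 and -199), held 50.9% of the variance. Values without sham 1, and with the off-tissue median as a covariate, therefore stand beside the gene groups below. The covariate was added after the arrays had been seen. Its slope is fitted within groups, where sham varies most through sham 1, so it partly repeats the fit without sham 1. The off-tissue level also differs between groups, so the adjustment extrapolates between them.

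**Figure D1:**
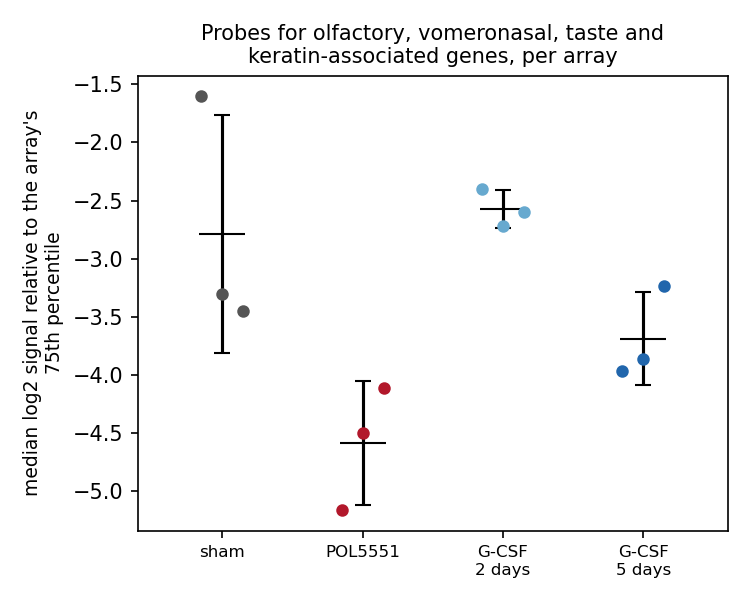
Median log2 level of the 1554 probes for off-tissue genes on each of the 12 arrays, relative to the array's 75th percentile, with each point an array, the black bar the group mean and the error bar the SD. Sham 1 lies at -1.60 and the POL5551 arrays lie between -5.16 and -4.11.

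The first comparison asked how blocking CXCR4 for 2 weeks changed the stem cells. The gene with the smallest p was Cd53, a tetraspanin of leukocyte membranes (probe on chromosome 3, 106565046 to 106566140). Its level was -0.23 ± 0.50 after POL5551 and -5.39 ± 0.72 in sham, a log2 difference of 5.16 (SE 0.442, adjusted p = 0.00189), and 1 of the 3 sham arrays had it well above background. Borcs5, a subunit of the complex that positions lysosomes (chromosome 6, 134660740 to 134660799), rose at least 5.96-fold (adjusted p = 0.00344), as it was not well above background on any sham array. Socs3, the feedback inhibitor of cytokine receptors that signal through STAT3 (chromosome 11, 117827480 to 117827539), rose by 1.84 (SE 0.387, adjusted p = 0.0428). Gadd45g, a stress-inducible gene (chromosome 13, 51943733 to 51943792), rose by 1.53 (SE 0.301, adjusted p = 0.0377).

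Bounds of the form "at least N-fold" set the brighter group's mean against the lowest signal well above background on the arrays of the dimmer group. Ebf3, a transcription factor of the early B-cell factor family (chromosome 7, 144385490 to 144385549), rose at least 11.2-fold after POL5551 (adjusted p = 0.0197), as no sham array had it well above background. Hvcn1, a voltage-gated proton channel, rose at least 5.8-fold and Rbp4, the plasma carrier of retinol, at least 4.01-fold, with adjusted p of 0.0293 and 0.0229. Tlr12, a Toll-like receptor, rose by 4.41 (SE 0.884, adjusted p = 0.0393, well above background on 2 of the 3 sham arrays) and Hp, haptoglobin, by 3.73 (SE 0.856, adjusted p = 0.0493). Gdpd2, a glycerophosphodiesterase, was 4.97 higher (SE 1.08, adjusted p = 0.0457) with 1 sham array well above background, but another probe of the gene went the other way. With only probes above background on all 12 arrays its difference was -1.38.

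Among the genes that fell after POL5551 was Cnn3, calponin 3, an actin-binding protein (chromosome 3, 121127170 to 121127229). Its probe was well above background on all 3 sham arrays and on none of the POL5551 arrays (adjusted p = 0.00816). Dydc1 (chromosome 14, 41905295 to 41905354), which was not well above background on any POL5551 array, was at least 12-fold lower (adjusted p = 0.00197). Tmem139 was at least 10.9-fold lower, Ccdc148 at least 10.7-fold and Kcna2, a voltage-gated potassium channel, at least 7.92-fold, with adjusted p of 0.00238, 0.00975 and 0.00683. Inhbe, a subunit of activin E, was at least 12.4-fold lower and the olfactory receptor Olfr1018 at least 10.8-fold (adjusted p = 0.0303 and 0.0403). Mcpt1, a mast cell protease well above background on 1 of the 3 POL5551 arrays, fell by 4.95 (SE 0.975, adjusted p = 0.0377).

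In all, limma called 758 of 33191 genes at an adjusted p under 0.05, of which 59 rose and 699 fell. Of the genes that fell, 64 were off-tissue genes and 432 were gene models, clones or accessions with no gene symbol, and no off-tissue gene rose. Scaling mattered for this split. The median log2 difference of all genes was -0.52 and 7.78% of calls were higher. That share was 23.6% with median scaling (52 higher, 168 lower, median of all genes -0.12), 20.0% with quantile normalization (18 and 72, median -0.20), 21.4% with normexp and quantile normalization (6 and 22, median -0.14), and 25.8% with the authors' own values (16 and 46, median -0.20). Slides 1 and 2 held arrays of both groups. With slide as a block 1106 genes were called, and the differences within slides 1 and 2 were 2.53 and 1.91 for Socs3.

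The gene lists fixed in advance were tested with camera, which sets a list's members against all other genes, and 17 of 29 lists were higher after POL5551. With an estimated correlation between genes none of the 29 passed, the 17 having adjusted p from 0.269 to 0.571, and 3 lists had an unadjusted camera p under 0.05. Oxidative phosphorylation genes stood highest among the pathway lists, with a mean log2 difference of 0.86 and 39 of 40 members higher (adjusted p = 1.06e-10). Uqcrc1, a subunit of complex III, was 1.23 higher and Cycs, cytochrome c, 1.06 higher, neither past the threshold alone, as was Atp5g1 at -1.23. The S phase and DNA replication list had a mean of 0.82, with 37 of 42 members higher (adjusted p = 9.9e-10). None of its members passed among all genes, while 11 higher members and 1 lower passed adjusted over the list alone. Clspn, a replication checkpoint mediator, was at 2.26 (SE 0.529, adjusted p = 0.0521) and Rrm1, a subunit of ribonucleotide reductase, at 1.17 (SE 0.302, adjusted p = 0.0607), against -1.38 for the primase subunit Prim2. The G2/M list had a mean of 0.70 (adjusted p = 2.4e-08), with Bub1b, a spindle checkpoint kinase, at 2.05 and Kif2c, a mitotic kinesin, at 1.43, against -1.87 for Tpx2 and -1.46 for Hmmr. Clspn and Bub1b were each well above background on 2 of the 3 sham arrays. The glycolysis and hypoxia list (mean 0.83, adjusted p = 1.02e-08) and the MYC target list (mean 0.66, adjusted p = 9.21e-08) were higher too. Ndrg1 (1.72) led the first, and Nolc1 (1.03) and Rrs1 (1.00), both of ribosome assembly, the second. No member of these lists passed among all genes.

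Other higher lists held genes of marrow retention and cytokine signalling. The list of the CXCR4 axis, adhesion and niche retention had a mean of 0.58, with 30 of 42 members higher (adjusted p = 6.34e-06). Its chemokine Cxcl12, the ligand of CXCR4 (chromosome 6, 117131227 to 117131286), also a member of the stromal list, was 3.47 higher (SE 0.942, adjusted p = 0.0643), and the integrin Itgb2 1.46 higher (adjusted p = 0.0593). The G-CSF receptor and STAT target list had a mean of 0.60 (adjusted p = 3.85e-05), and 2 of its 30 members, Socs3 and Hp, rose. The transcription factor Junb was at -1.26. The HSC identity list had a mean of 0.49, with 32 of 40 members higher (adjusted p = 3.85e-05), led by the angiopoietin receptor Tek (1.46, well above background on 2 of the 3 sham arrays) and Cd27 (1.46), with Mecom at -1.35 and Trpc6 at -0.71. The list of stromal and osteoblast markers had the largest mean, 1.53 (16 of 23 members higher, adjusted p = 1.5e-05). Pdgfrb, a receptor of perivascular cells, rose by 3.62 (SE 0.688, adjusted p = 0.0335), 6 members passed adjusted over the list alone, and Adipoq, adiponectin, was 3.71 higher (adjusted p = 0.0524), against -0.82 for Pdgfra and -0.57 for Kitl. Pdgfrb was well above background on 2 of the 3 sham arrays. The stromal genes Cxcl12 and Adipoq and the genes Hp, Gdpd2 and Ebf3, compared after their values were seen, followed each other over the mice. Within its group, each was lowest on POL5551 mouse 2 and on 5-day mouse 2 and highest on 2-day mouse 3.

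Other lists that were higher were the unfolded protein response (mean 0.47, adjusted p = 0.000145), quiescence (0.45, 2e-04), interferon gamma (0.48, 0.000365), type I interferon (0.36, 0.00052), p53 (0.52, 0.000582), ribosomal protein (0.23, 0.00231), megakaryocyte (0.33, 0.00811) and cholesterol synthesis (0.23, 0.00933) lists. Gtse1, of the p53 list, rose at least 3.00-fold (adjusted p = 0.0463), and Gp1ba, the platelet glycoprotein Ib alpha chain, at least 2.74-fold (adjusted p = 0.0416). Members that did not pass included the foldase Pdia4 (1.38) and Creld2 (1.18) against Hyou1 (-0.92) and Ddit3 (-0.84), and Gfi1 (1.51) against Nr4a2 (-0.82) and Cdkn2c (-0.52). In the type I interferon list Trim30a was at 0.92 and Isg15 at -0.79. In the cholesterol list Ebp was at 1.62 and Lss at -0.92, and in the ribosomal list Rpl8 was at 1.55 and Rps4x at -1.31. Rpl8 was at 1.032 on sham 1, against 4.43 and 4.436 on shams 2 and 3 and 4.735 to 4.999 on the POL5551 arrays.

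With slide as a block all 17 lists passed (highest adjusted p 0.00232). Their means within slide 1 ran from 0.60 to 1.75 and within slide 2 from -0.14 to 1.07, with the type I interferon, interferon gamma and cholesterol lists below 0 there. Without sham 1, 13 lists passed, and the adjusted p of the interferon gamma, ribosomal, cholesterol and megakaryocyte lists became 0.0757, 0.976, 0.202 and 0.116. The mean of the stromal list rose to 1.93 and the means of all the others fell. They fell to 0.09 for HSC identity, 0.05 for type I interferon, 0.41 for oxidative phosphorylation, 0.31 for MYC targets and 0.64 for G2/M. Camera sets a list against the other genes, so a list with a small mean can pass. With the off-tissue median as a covariate only the stromal (adjusted p = 2.16e-09) and G2/M (0.0395) lists of the 17 were still higher. The ribosomal (mean -0.56, adjusted p = 1.06e-05), HSC identity (-0.46, 0.0017), interferon gamma (-0.59, 0.00234), type I interferon (-0.36, 0.0478) and cholesterol (-0.40, 0.0478) lists were lower, and the macrophage list was higher (0.60, 0.0478). Single genes rested on single arrays to different degrees. Leaving out any 1 of the 12 arrays kept Cd53, Borcs5, Cnn3, Dydc1, Tmem139, Ccdc148 and Kcna2 past the threshold. Ebf3 and Rbp4 lost it without sham 1 or POL5551 mouse 1 (adjusted p from 0.0593 to 0.0909), Hvcn1 without sham 1 or POL5551 mouse 1 or 2 (0.0743 to 0.11), and Socs3 without sham 1 (0.105), POL5551 mouse 1 (0.144) or mouse 2 (0.0907), and without any 1 of the 2-day mice or the 5-day mice 1 or 2 (0.055 to 0.069). Gadd45g lost it without sham 1, any 1 POL5551 or 2-day mouse, or 5-day mouse 2 (0.0505 to 0.133). Inhbe lost it without sham 1 (0.112) or POL5551 mouse 1 (0.122) or 2 (0.0752). Tlr12, Pdgfrb, Hp, Gdpd2, Gtse1, Gp1ba, Olfr1018 and Mcpt1 each lost it without 5 to 9 of the 12 arrays, POL5551 mice 1 and 2 among them for each gene. Under the off-tissue covariate no gene was called by limma, with 1819 at an unadjusted p under 0.05. The count was 71 without sham 1, 2502 without sham 2, 4665 without sham 3, 60 and 114 without POL5551 mice 1 and 2, 242, 270 and 250 without the 2-day G-CSF mice 1, 2 and 3, and 459 and 359 without the 5-day mice 1 and 2.

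The markers of the sort and of the CXCR4 pathway, named in advance, gave no call after POL5551 other than Socs3. Cxcr4 itself (chromosome 1, 130485079 to 130485138) was 0.75 higher (SE 0.541, adjusted p = 0.298), and Ackr3, the second receptor of Cxcl12, was well above background on 1 array of each group. The Cxcr4 difference rests on sham 1, at 1.357, as shams 2 and 3 were at 3.793 and 3.474 and the POL5551 arrays at 3.557 to 3.689. Csf3r, the G-CSF receptor, was at -0.88 (SE 0.347, adjusted p = 0.114). Kit was at -0.04, Ly6a, which encodes Sca-1, at 1.05, and the SLAM markers Slamf1, well above background on 2 of the 3 sham arrays, and Cd48 at 1.53 and -0.22. The progenitor markers Cd34 and Flt3 were at 1.21 and -0.46, Procr, of stem cells, at 0.96, and the proliferation marker Mki67 at 0.93. Sham 1 lay below shams 2 and 3 for Ly6a (-1.837 against 0.915 and 0.771) and Slamf1 (-4.117 against -0.959 and -1.41). It did so too for Procr (-0.082 against 1.634 on both) and Cd34 (-0.817 against 1.02 and 0.666), and lay above them for Csf3r (6.86 against 5.889 and 5.518). The differences of these genes therefore rest partly on sham 1.

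**Figure D2:**
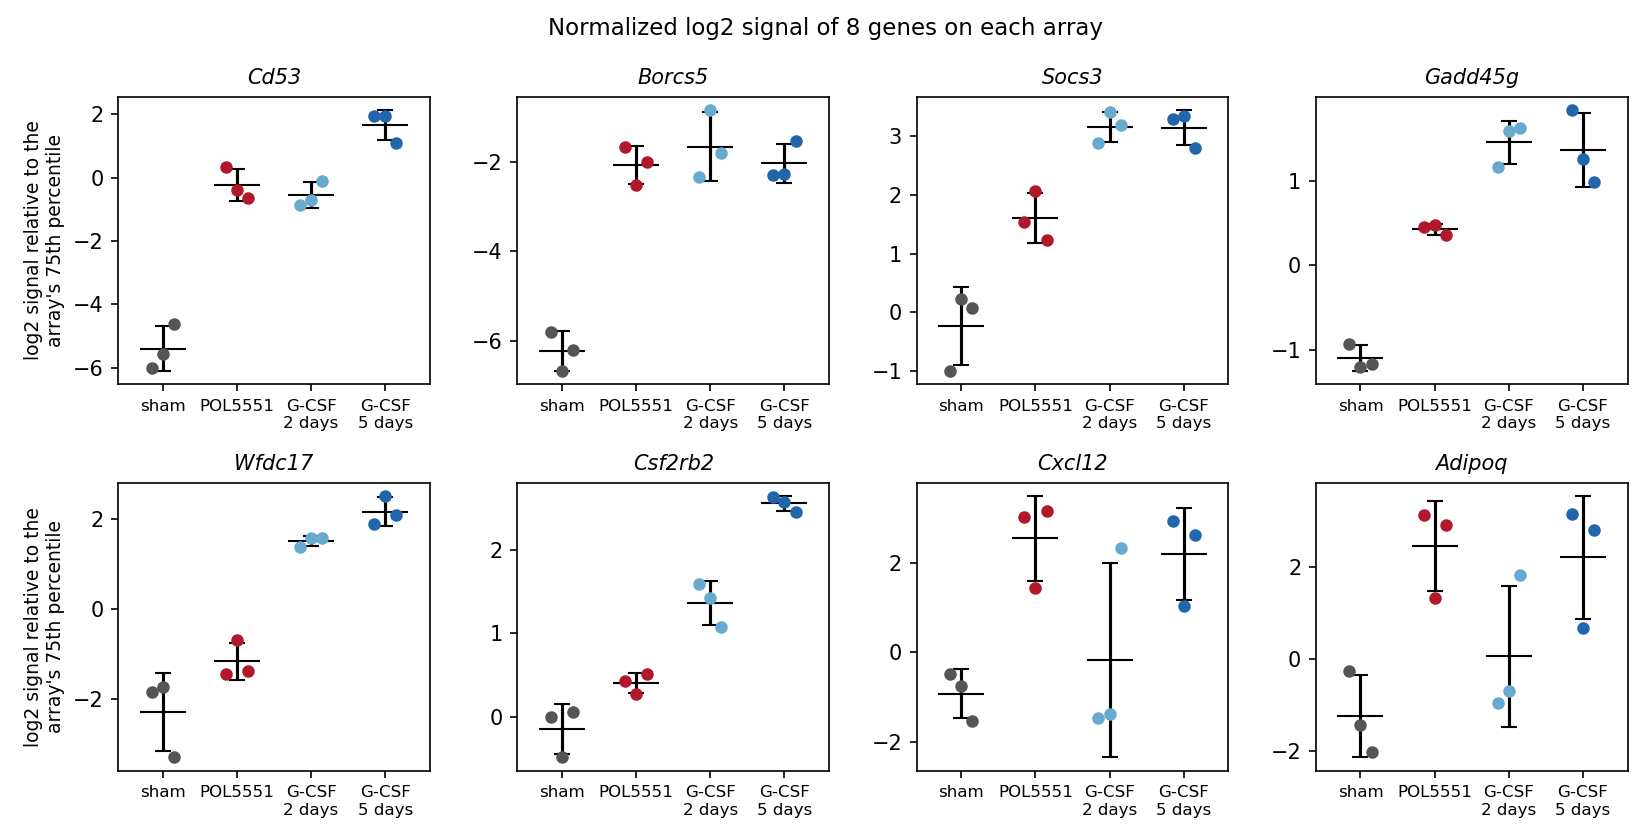
Log2 level of Cd53, Borcs5, Socs3, Gadd45g, Wfdc17, Csf2rb2, Cxcl12 and Adipoq on each of the 12 arrays, relative to the array's 75th percentile, with each point an array, the black bar the group mean and the error bar the SD. Cd53 lies at a mean of -5.39 in sham and at -0.23, -0.56 and 1.67 in the POL5551, 2-day and 5-day groups.

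The second comparison set 2 days of G-CSF against sham. The sample labels name no injections for the sham mice and no operation for the G-CSF mice. Injection and surgery were therefore not separated from G-CSF, here or at 5 days. Again Cd53 rose, by 4.83 (SE 0.442), and Borcs5 rose at least 7.87-fold, with an adjusted p of 0.00738 for each. Wfdc17, a small secreted protein with a WAP domain (chromosome 11, 83518443 to 83519627), rose by 3.78 (SE 0.426, adjusted p = 0.0162), from a sham level of -2.28 ± 0.87. Socs3 rose by 3.38 (SE 0.387, adjusted p = 0.0162) and Gadd45g by 2.56 (SE 0.301, adjusted p = 0.0177). The olfactory receptor Olfr729 rose at least 1.45-fold (adjusted p = 0.0292). limma called 11 genes, 10 higher and 1 lower. The lower one, the transcript AK047799 (adjusted p = 0.0244), was well above background on 2 of the 3 sham arrays and on no 2-day array, and lies outside the naming rule, so it was chosen after its values were seen. The median log2 difference of all genes was 0.10.

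None of the other markers named below, chosen in advance, passed after 2 days. Cxcr4 was at -0.80 (SE 0.541, adjusted p = 0.721) and Cxcl12 at 0.75 (SE 0.942). On the 2-day arrays Cxcr4, at 1.733 to 2.547, lay above sham 1 (1.357) and below shams 2 and 3 (3.793 and 3.474). The size of its difference therefore rests partly on sham 1. Csf3r was at -0.36, Kit at -0.27 and Procr at -0.24. Cd34 was at 0.67, Cd48 at 0.41, Flt3 at 0.33, Slamf1 at 0.30, Mki67 at 0.28 and Ly6a at 0.23, and Ackr3 was well above background on 1 array of each group. Ly6a, at -0.195 to 0.369 on the 2-day arrays, lay above sham 1 (-1.837) and below shams 2 and 3 (0.915 and 0.771). Slamf1, at -2.113 to -1.39, lay above sham 1 (-4.117), while shams 2 and 3 were at -0.959 and -1.41. The signs of both genes therefore rest on sham 1. Cd34, at 0.68 to 1.311, lay around shams 2 and 3 (1.02 and 0.666).

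As groups, 7 lists were lower and 2 higher after 2 days. All 9 calls were lost with an estimated correlation, where the smallest adjusted p was 0.675 and no list had an unadjusted camera p under 0.05. The list of the interferon gamma response and MHC class II was lower, with a mean of -0.43 and 27 of 36 members lower (adjusted p = 0.000371). B2m, the light chain of MHC class I, was at -1.13 (SE 0.258, adjusted p = 0.308), against 0.86 for H2-D1. The sign of H2-D1 rests on sham 1, at 0.976, as shams 2 and 3 were at 4.991 and 5.069 and the 2-day arrays at 4.144 to 5.073. Markers of dendritic cells, B cells and macrophages outside that list, which carry MHC class II too, had a mean of 0.16 ± 0.06 (SE over 38 genes). The HSC identity list had a mean of -0.19, with 27 of 40 members lower (adjusted p = 0.00477). Angpt1, the ligand of Tek, was at -1.61 (SE 0.302, adjusted p = 0.163) and the transcription factor Fli1 at -1.19, against 0.79 for Nkx2-3 and 0.54 for Itga2b. The quiescence list had a mean of -0.26 (adjusted p = 0.00863). Cdkn1c, the cell cycle inhibitor p57 (chromosome 7, 150644297 to 150644356), was at -1.78 (SE 0.412, adjusted p = 0.313) and Tob1 at -1.81, against 1.40 for Btg1. Oxidative phosphorylation (mean -0.19, 0.00477), type I interferon (-0.25, 0.00477), cholesterol synthesis (-0.30, 0.00693) and MYC targets (-0.17, 0.00936) were lower, where the second number is the adjusted p. Their lowest-p members were Ndufa4 (-0.77) and Cox7a2 (-0.65), Ifit1 (-1.51) and Rsad2 (-0.60), Idi1 (-1.62) and Hsd17b7 (-1.38), and Mycn (-1.02) and Polr1a (-1.02). Tob1 and Ifit1 were well above background on 2 of the 3 2-day arrays.

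The stromal list was higher after 2 days, with a mean of 0.80 (adjusted p = 0.00882), as was the G2/M list, with a mean of 0.43 (adjusted p = 0.0403). Pdgfrb was at 2.59 and the osteocalcin gene Bglap at 0.88 in the first, and Dlgap5, a spindle protein, at 2.71 and Cdc25c at 0.77 in the second. Pdgfrb and Dlgap5 were well above background on 2 of the 3 sham arrays. No member of the 9 lists passed among all genes. Adjusted over the list alone, 1 lower member passed in each of the interferon gamma, HSC identity and quiescence lists and 2 in the cholesterol list.

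Arrays of the shams decided much of this comparison. Without sham 1 the interferon gamma and HSC identity lists had means of -0.91 and -0.59 (adjusted p = 3.13e-10 and 7.79e-09), 14 lists passed, 13 of them lower, and 166 genes were called, 138 higher and 28 lower. Without sham 2 only 1 list passed, and without sham 3 none did by camera (5 at an unadjusted p under 0.05), so none of the 9 lists was called in either case, the interferon gamma list having an adjusted p of 0.0878 and 0.185. The G2/M list was lost without sham 1 (0.388), POL5551 mouse 1 (0.0563) or 2-day mouse 2 (0.413) as well. The stromal list was lost without 2-day mouse 3 (0.351), and the HSC identity, MYC and oxidative phosphorylation lists without 2-day mouse 1 (0.0509, 0.0677 and 0.073). With the off-tissue covariate the interferon gamma (adjusted p = 0.025) and G2/M (0.025) lists passed and the other 7 of the 9 did not. Their adjusted p was 0.0613 for the stromal and type I interferon lists, 0.0618 for quiescence, 0.0756 for cholesterol, 0.128 for HSC identity and 0.211 for MYC and oxidative phosphorylation. The gene count was 4 without sham 2, 2, 5 and 3 without the 2-day mice 1, 2 and 3, and 7 without the 5-day mouse 1. Cd53 and Borcs5 stayed past the threshold without any 1 array, and Wfdc17, Socs3 and Gadd45g lost it without any 1 of the 2-day mice (adjusted p from 0.084 to 0.126), Gadd45g also without sham 2 (0.0909) or sham 3 (0.066). Olfr729 passed only without sham 1 or POL5551 mouse 1. The 2-day arrays filled a slide of their own, so no value within slides exists, and slide as a random block left 11 genes.

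After 5 days of G-CSF, the comparison that follows the usual length of treatment for mobilization, Cd53 had risen by 7.06 (SE 0.442, adjusted p = 0.000149), to 1.67 ± 0.49. Wfdc17 rose by 4.43 (SE 0.426, adjusted p = 0.00693), Socs3 by 3.37 (SE 0.387, adjusted p = 0.00942) and Gadd45g by 2.47 (SE 0.301, adjusted p = 0.0118). Csf2rb2, a beta subunit of the interleukin 3 receptor (chromosome 15, 78113126 to 78113185), rose by 2.69 (SE 0.281, adjusted p = 0.00779), from -0.14 ± 0.30 to 2.55 ± 0.09. Muc1, a membrane mucin, rose by 3.21 (SE 0.389, adjusted p = 0.0118). Rcvrn, recoverin, a calcium-binding protein known from photoreceptors, rose at least 15.6-fold (adjusted p = 0.00942), Cltrn, collectrin, at least 6.74-fold (adjusted p = 0.00942), and Borcs5 at least 6.11-fold (adjusted p = 0.00779).

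Of 22 genes called after 5 days, 16 rose and 6 fell, and the median of all genes was -0.13. Among those that fell, the olfactory receptor Olfr1499 was at least 2.9-fold lower (adjusted p = 0.0293), and the other 5 were gene models, clones or accessions. The share of higher calls was 72.7%, against 89.5% with normexp and quantile normalization (17 higher, 2 lower). None of the other markers chosen in advance and named here passed. Cxcl12 was 3.12 higher (SE 0.942, adjusted p = 0.327) and Cxcr4 at -0.20 (SE 0.541, adjusted p = 0.896). Csf3r was at -0.79, Procr at -0.43 and Kit at -0.37, while Cd34 was at 1.37, Ly6a at 1.05, Slamf1 at 0.62, Mki67 at 0.53, Cd48 at 0.33 and Flt3 at 0.09. On the 5-day arrays Cxcr4, at 2.426 to 2.864, lay above sham 1 (1.357) and below shams 2 and 3 (3.793 and 3.474). Ly6a (0.452 to 1.443) and Slamf1 (-2.195 to -0.635) lay above sham 1 (-1.837 and -4.117) and around shams 2 and 3. The differences of these genes therefore rest partly on sham 1. Ackr3, well above background on 2 of the 5-day arrays and 1 sham array, was at 0.03.

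Of the lists, 8 were higher after 5 days and none passed lower. All 8 calls were lost with an estimated correlation (smallest adjusted p 0.593), where 2 lists had an unadjusted camera p under 0.05. The stromal list led with a mean of 1.30 and 18 of 23 members higher (adjusted p = 0.000165). Pdgfrb was 4.17 higher (adjusted p = 0.072) and Adipoq 3.46 higher (adjusted p = 0.253), against -1.18 for Runx2 and -0.44 for Pdgfra, and 5 members passed adjusted over the list alone. The G-CSF receptor and STAT target list had a mean of 0.58 (adjusted p = 0.000338). Socs3 rose, 4 members passed adjusted over the list alone, the kinase Pim2 was at 2.42 with 2 of the 3 sham arrays well above background, and Cebpb was at -1.07. G2/M genes had a mean of 0.41 (adjusted p = 0.000338), with Bub1b at 1.55 and Kif2c at 1.18 against Hmmr at -1.08, and S phase genes a mean of 0.36 (adjusted p = 0.00121), with Clspn at 1.30 and the transcription factor E2f1 at 1.21 against Prim2 at -0.92. MYC targets (mean 0.40, 0.000393), glycolysis (0.39, 0.00293), the CXCR4 axis (0.32, 0.00661) and the unfolded protein response (0.28, 0.0337) followed, the second number being the adjusted p. Their members with the smallest p were Nolc1 (0.92) and Rrs1 (0.83), Ndrg1 (2.03), Cxcl12 and Itgb3 (1.22), and Pdia4 (1.36), with Trib3 at -1.05.

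Without sham 1 the stromal (3.04e-08), G2/M (0.00352) and STAT target (0.035) lists were still higher by adjusted p, and the lymphoid priming list was higher too (0.0468). The interferon gamma (2.85e-06), ribosomal (2.85e-06), HSC identity (0.00352), type I interferon (0.00352), cholesterol (0.0145) and oxidative phosphorylation (0.0281) lists were then lower, with means from -0.55 to -0.23. The S phase, CXCR4 axis, MYC, glycolysis and unfolded protein lists were lost without sham 1 (0.585, 0.794, 0.518, 0.794 and 0.91), and the last also without 5-day mouse 2 (0.237). Without sham 2, 16 lists passed. With the off-tissue covariate the stromal list was the only higher one (adjusted p = 2.08e-06), and the interferon gamma (5.43e-07), ribosomal (8.22e-06), oxidative phosphorylation (3.92e-05), HSC identity (6.11e-05), type I interferon (0.000292) and cholesterol (0.000736) lists were lower. No slide held both sham and 5-day arrays. With slide as a fixed block, which links them through POL5551 arrays, limma called 0 genes (2490 at an unadjusted p under 0.05), Cd53 having an adjusted p of 0.191. That fit rests on 1 array of the 5-day group, mouse 2, since slides 4 and 6 held 1 array each. The stromal list then had a mean of -0.37, while the means of the other 7 lists ran from 0.272 to 1.171. Of the lists that had not passed before, oxidative phosphorylation lay higher, with a mean of 1.027, and mature neutrophil lower, at -1.012. As a random block, with a correlation of 0.0178 within slides, slide left 19 genes. The gene count was 55 without sham 3, 3 without 5-day mouse 1 and 1, Cd53, without 5-day mouse 2. Borcs5, Socs3, Csf2rb2, Rcvrn, Cltrn, Muc1 and Gadd45g lost the threshold without 5-day mouse 1 or 2 (adjusted p from 0.0525 to 0.0996), Wfdc17 without mouse 2 (0.0513), and Muc1 and Gadd45g without sham 2 (0.0513 and 0.0593). Olfr1499 lost it without any 1 of 8 arrays (0.0505 to 0.152), and kept it without sham 3, POL5551 mouse 3, 2-day mouse 2 or 5-day mouse 3.

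**Figure D3:**
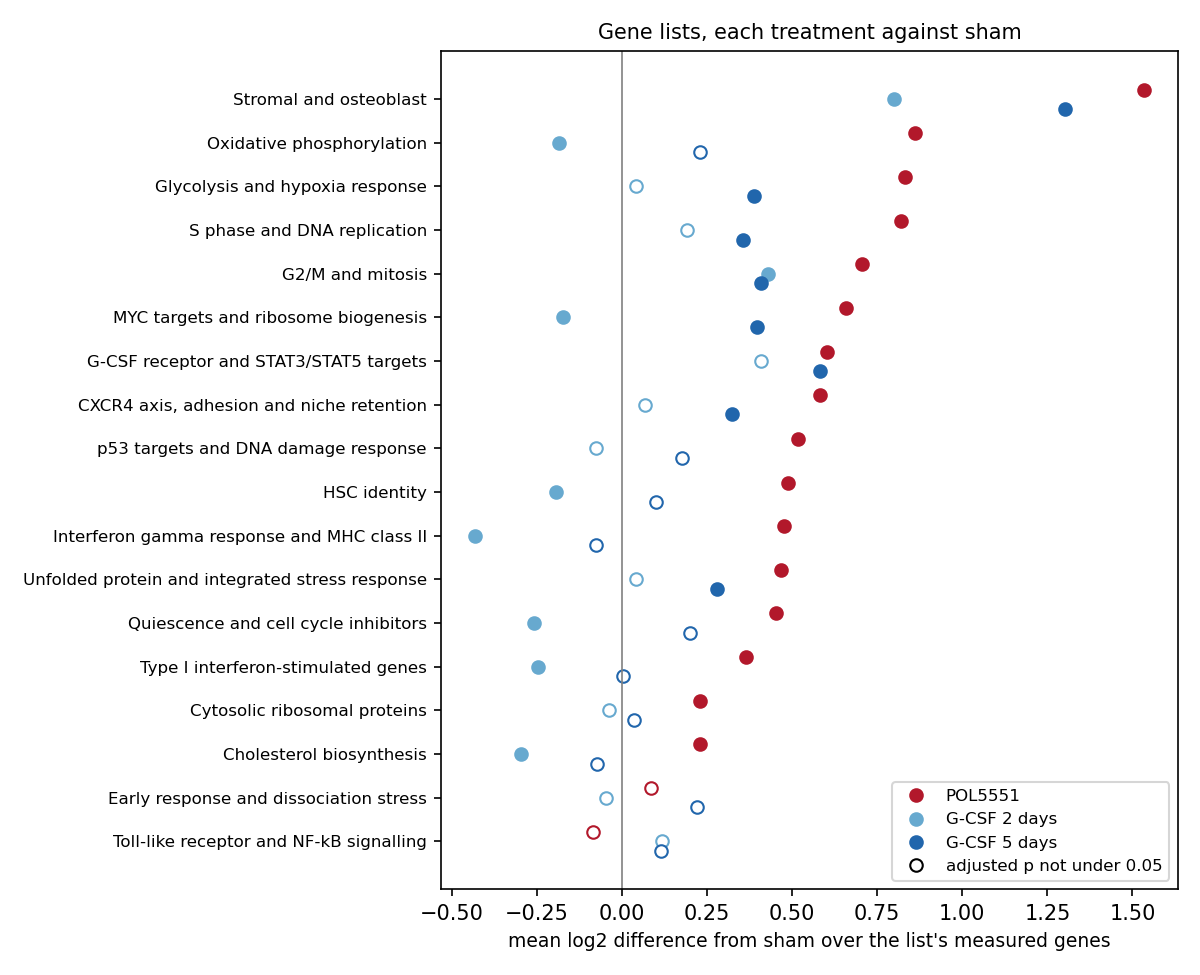
Mean log2 difference from sham of the members of the 17 pathway lists and the stromal and osteoblast list after POL5551, 2 days and 5 days of G-CSF, with each point a list and filled points an adjusted camera p under 0.05. The stromal list lies at 1.53, 0.80 and 1.30, and the interferon gamma list at 0.48, -0.43 and -0.08.

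The longer and shorter G-CSF courses were also set against each other directly. No gene passed by limma between 5 and 2 days, with 5370 genes at an unadjusted p under 0.05. The genes with the smallest p were Zbtb8a, a zinc finger protein, at least 3.89-fold higher at 5 days (adjusted p = 0.0733), Ddx11, a DNA helicase, at least 3.05-fold higher (adjusted p = 0.0733), and Tmem199, at least 1.92-fold higher (adjusted p = 0.25). Lower at 5 days, with an adjusted p of 0.25 each, were Zmynd12 (-1.88, SE 0.323) and the vomeronasal receptor V1ra8 (at least 2.22-fold). The median of all genes was -0.27.

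Between the courses 16 lists were higher at 5 days and 1 lower. With an estimated correlation no list passed (smallest adjusted p 0.389, 1 list at an unadjusted camera p under 0.05). MYC targets stood first, with a mean of 0.57 and 34 of 38 members higher (adjusted p = 2.43e-08), led by Polr1a (1.61) and Rrs1 (1.09), against -0.68 for Ubtf. Oxidative phosphorylation had a mean of 0.41 and 36 of 40 members higher (adjusted p = 7.42e-06), with Cycs at 0.99 and Cox7a2 at 0.84. Quiescence genes had a mean of 0.46 and 27 of 29 members higher (adjusted p = 3.37e-05), with Tob1, well above background on 2 of the 3 2-day arrays, at 1.93, against -1.37 for Btg1. The HSC identity list had a mean of 0.29 (adjusted p = 0.000332), with Tek at 1.71 and Fli1 at 1.11. In the CXCR4 axis list (mean 0.26, adjusted p = 0.00113) the integrins Itgb2 and Itga4 were at 1.46 and 1.34 and the chemokine receptor Cxcr3, well above background on 1 of the 3 5-day arrays, at -3.63. The megakaryocyte list (mean 0.37, adjusted p = 0.00113) had Pf4, platelet factor 4, at 1.93. The early response list (mean 0.26, adjusted p = 0.00113) had Btg2 at 1.20 and Nr4a3 at -2.01. The interferon gamma list had a mean of 0.36 (adjusted p = 0.00201), with H2-DMa at 1.09, and the type I list 0.25 (adjusted p = 0.00201), with Trim30a at 0.76 and Eif2ak2 at -0.99.

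The other higher lists were glycolysis (mean 0.35, 0.000533), the unfolded protein response (0.24, 0.00756), cholesterol synthesis (0.22, 0.00967), S phase (0.17, 0.011), p53 targets (0.25, 0.0163), STAT targets (0.17, 0.0244) and ribosomal proteins (0.07, 0.0299), the second number being the adjusted p. Asns, asparagine synthetase, was at 1.28, Stard4 at 0.85, Ccne2, cyclin E2, at 1.52 with 2 of the 3 2-day arrays well above background, Hp at 2.03 and Rpl7 at 0.91, none past the threshold. The list of T and NK cell markers was lower, with a mean of -0.68 and 22 of 23 members lower (adjusted p = 0.0492), Cd4 being at -1.97 and Il2rb at -1.60, neither past the threshold. The median log2 difference of the off-tissue genes was -1.01, and with the off-tissue covariate none of the 17 calls held in its direction, while the ribosomal (adjusted p = 0.00186), S phase (0.012) and oxidative phosphorylation (0.0484) lists were lower and the stromal list was higher (0.0375). The T and NK list was lost without sham 1, sham 3, POL5551 mouse 3, 2-day mouse 2 or 3, or 5-day mouse 2 (adjusted p from 0.0503 to 0.244). The ribosomal list was lost without 2-day mouse 1 or 5-day mouse 2 or 3 (0.0649 to 0.171), the STAT list without 2-day mouse 1 (0.0634) or 5-day mouse 1 (0.174), and the S phase list without 5-day mouse 2 (0.074). Without sham 1, which enters through the spread alone, 14 genes were called, without sham 3 it was 3, and without 5-day mouse 3 it was 4. The 2-day arrays had a slide to themselves, and with slide as a random block no gene passed by limma (5201 at an unadjusted p under 0.05).

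The antagonist and the cytokine were compared at their longest courses, POL5551 for 14 days against G-CSF for 5 days, so their lengths differ. Of 20 genes called by limma, all were lower after POL5551, with a median of all genes of -0.28. Among the 20, 12 were gene models, clones or accessions with no gene symbol and 1 was an off-tissue gene. The median log2 difference of the off-tissue genes was -0.739. Cltrn was at least 8.47-fold lower (adjusted p = 0.00787), Rcvrn, well above background on 1 of the 3 POL5551 arrays, fell by 5.58 (SE 0.603, adjusted p = 0.0113), and Wfdc17 fell by 3.31 (SE 0.426, adjusted p = 0.0274), from 2.16 ± 0.32 to -1.16 ± 0.42. Tmem139 was at least 4.51-fold lower (adjusted p = 0.0274). Abca4, a lipid transporter known from photoreceptors, fell by 3.46 (SE 0.507, adjusted p = 0.043), with 1 of its 2 other probes in the same direction. No gene was higher, and the smallest p among the higher ones belonged to Stap2, a signalling adaptor (at least 3.35-fold, adjusted p = 0.0818), Cyp26b1, which degrades retinoic acid (2.89, adjusted p = 0.0921), and Ebi3, a subunit of interleukins 27 and 35 (2.42, adjusted p = 0.103). With the authors' own values 12.5% of the calls were higher (1 higher, 7 lower).

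Against G-CSF for 5 days, 15 lists were higher after POL5551. With an estimated correlation no list passed (smallest adjusted p 0.259, 3 lists at an unadjusted camera p under 0.05). Oxidative phosphorylation had a mean of 0.63 and 39 of 40 members higher (adjusted p = 9.22e-13), with Ndufa8 at 1.42 and Ndufa4 at 1.15. The S phase list had a mean of 0.47 (adjusted p = 3.22e-08), with Dut at 1.39 and the helicase subunit Mcm6 at 0.80. The interferon gamma list had a mean of 0.55 and 29 of 36 members higher (adjusted p = 4e-08), with Gbp4, an interferon-induced GTPase, at least 3.28-fold higher and the peptide transporter Tap2 at 1.05, and 1 member passed adjusted over the list alone. The HSC identity list had a mean of 0.39 (adjusted p = 1.13e-06), with Fgd5 at 1.14 and Clec1a at 0.87 against Itga2b at -1.02. The CXCR4 axis list had a mean of 0.26 (adjusted p = 0.000195), with Itgb2 at 1.02. The quiescence list (mean 0.25, adjusted p = 0.000568) had Cdkn1c at 1.53 and Gfi1 at 1.31, and the p53 list (mean 0.34, adjusted p = 0.000477) had the kinase Plk2 at 2.54.

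The remaining higher lists were glycolysis (mean 0.44, 6.81e-07), type I interferon (0.36, 5.96e-06), G2/M (0.30, 1.49e-05), MYC targets (0.26, 0.000101), ribosomal proteins (0.20, 0.00011), cholesterol synthesis (0.30, 0.00016), the unfolded protein response (0.19, 0.0019) and megakaryocyte markers (0.14, 0.0428), the second number being the adjusted p. Among their members Hif1a was at 1.25, Rsad2 at 0.85, Spc25 at 0.83, Nip7 at 0.65, Rpl35 at 0.52, Stard4 at 1.27, Ddit4 at 1.70 and Selp, P-selectin, at -1.82, none past the threshold. Slide 5 held 1 array of each group. With slide as a block limma called 0 genes (797 at an unadjusted p under 0.05), and of the 15 lists the interferon gamma (0.56, adjusted p = 9.35e-05), type I interferon (0.34, 0.0115) and CXCR4 axis (0.36, 0.0146) lists were still higher. The stromal (1.5, 1.06e-10) and mature neutrophil (0.87, 3.68e-05) lists also passed higher in that fit, which rests on 1 array of each group. They passed higher in 12 and 3 of 31 alternatives. With the off-tissue covariate 0 genes (2342 at an unadjusted p under 0.05) and 0 lists passed (4 at an unadjusted camera p under 0.05). The gene count was 91, 48 and 42 without shams 1, 2 and 3, 0, 0 and 10 without POL5551 mice 1, 2 and 3 (the first pair with 2120 and 3260 genes at an unadjusted p under 0.05), 13 and 8 without 2-day mice 1 and 3, and 3, 9 and 1 without 5-day mice 1, 2 and 3. Cltrn lost the threshold without POL5551 mouse 1 (adjusted p = 0.0543) or mouse 2 (0.0728), and Rcvrn without the same mice (0.0543 and 0.0759) or 5-day mouse 1 (0.0521) or mouse 3 (0.0807). Wfdc17 lost it without any 1 array of either group or 2-day mouse 1 or 3 (0.0505 to 0.138), Tmem139 without any 1 array of either group or 2-day mouse 3 (0.0516 to 0.138), and Abca4 without any 1 treated array (0.072 to 0.213). The megakaryocyte list was lost without POL5551 mouse 1 (0.0529) or 2 (0.166) or 5-day mouse 3 (0.151), and the quiescence list without 5-day mouse 3 (0.105).

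Across the 4 groups the moderated F test of limma called 447 genes. That count was 7671, 2190 and 1874 without shams 1, 2 and 3, 55, 90 and 266 without POL5551 mice 1, 2 and 3, 61, 173 and 91 without 2-day mice 1, 2 and 3, and 213 and 217 without 5-day mice 1 and 2.

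Finally, the 3 treatments were set side by side for what they shared. Cd53, Borcs5, Socs3 and Gadd45g rose in all 3 comparisons with sham. Wfdc17 rose after both courses of G-CSF. After POL5551 it was 1.12 higher than in sham (adjusted p = 0.108), and it was lower than after 5 days of G-CSF in the direct comparison. POL5551 and 5 days of G-CSF shared 7 higher and 6 lower genes. Among the higher ones were also Tgfbi, a secreted matrix protein (1.67 and 2.57), and Ddx11, well above background on no sham array, which were chosen after their values were seen, and among the lower ones Olfr1499. Independent lists of these sizes would share 0.0284 and 0.126 genes. The 2 courses of G-CSF shared 6 higher genes, where independent lists would share 0.00482, and POL5551 and 2 days of G-CSF shared 4, where they would share 0.0178. In 100 simulations of unchanged groups against the same shams the median number shared was 0 for each pair, and the highest were 34, 41 and 1397 in the order given.

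Across genes, which are not independent replicates, the log2 differences of POL5551 and 5 days of G-CSF had a Pearson r of 0.741, against a median of 0.606 in the simulations (95% of them from -0.187 to 0.895). Their covariance was 0.744, against 0.22 simulated. For the 2 courses of G-CSF r was 0.39 (simulated 0.528, from -0.423 to 0.873) and the covariance 0.242 (simulated 0.166). For POL5551 and 2 days of G-CSF r was 0.0425 (simulated 0.575, from -0.274 to 0.939) and the covariance 0.0374 (simulated 0.201). The 3 shams cannot be split into parts of 2 or more, so part of any excess may come from the shared controls. Single arrays moved these values. Shared genes of POL5551 and 5 days of G-CSF numbered 7 and 46 without shams 1 and 3, 7 and 6 without POL5551 mice 1 and 2, and 2 and 1 without 5-day mice 1 and 2. Those of the G-CSF courses numbered 13 without sham 1, 2, 2 and 3 without 2-day mice 1, 2 and 3, and 2 and 1 without 5-day mice 1 and 2, and r was 0.598 without sham 3. Those of POL5551 and 2 days of G-CSF numbered 2 without POL5551 mouse 2, 2-day mouse 1 or 2, or 5-day mouse 2. Their r was -0.0488, 0.301 and 0.349 without shams 1, 2 and 3, and 0.11 and -0.0119 without 2-day mice 1 and 2.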

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

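The tests chosen after the result was seen were the covariate tests of Cd53, Borcs5 and the stromal list and the test of the stromal list without sham 1. The tests of scaling, genomic DNA, 3' bias, the chromosome segment and stromal covariation had their predictions written first.

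Between 5 and 2 days of G-CSF 17 gene lists passed by a direct test at the preset correlation of camera, and these were looked at more closely for that reason. None of the 17 passed with an estimated correlation between genes, where the smallest adjusted p was 0.389. Mean log2 differences of 5 days from 2 days were 0.569 for MYC targets, 0.457 for quiescence, 0.414 for oxidative phosphorylation, 0.369 for megakaryocyte markers, 0.356 for interferon gamma, 0.348 for glycolysis and 0.294 for HSC identity. They were 0.264 for the early response, 0.256 for the CXCR4 axis, 0.252 for p53, 0.251 for type I interferon, 0.235 for the unfolded protein response, 0.224 for cholesterol synthesis, 0.174 for STAT targets, 0.166 for S phase and 0.073 for ribosomal proteins. The value was -0.682 for T and NK markers. With the off-tissue median as a covariate none of the 17 calls held, though not every list changed direction. The S phase (-0.36, adjusted p = 0.012), ribosomal (-0.412, 0.00186) and oxidative phosphorylation (-0.302, 0.0484) lists were then lower. The median log2 difference of the off-tissue genes between the groups was -1.013.

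Off-tissue genes were highest on sham 1 and lowest on the POL5551 arrays. After quantile normalization the array medians still spanned 2.305 on the log2 scale, with a spread within groups of 0.694, which argues against the scaling of the arrays. The 3' minus 5' difference over 5308 transcripts had a Spearman rho of -0.224 with the off-tissue median (permutation p = 0.485, Pearson r = -0.28, permutation p = 0.378, 2 relations, adjusted 0.485 and 0.378, r = -0.432 without POL5551 mouse 1 and sham 1). That rho is below the size set in advance for no relation. With 12 arrays it is too uncertain to argue against 3' bias. The second relation, with the 75th percentile of the signal, is not read, since the off-tissue median is taken relative to that percentile. Low input of RNA was not tested. Genomic DNA in the labelled cDNA may remain. The 11 off-tissue probes that cross an exon junction, which genomic DNA would not match, rose on sham 1 by 61.6% as much as the 1513 others (95% bootstrap interval 55.3 to 94.9), too few probes to settle it, and the labels state a digestion of DNA. No biological explanation was tested.

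Cd53 and Borcs5 were dim on the 3 sham arrays and bright on the 9 treated arrays. A passenger segment around the genes is not settled. Of 286 genes within 5 Mb, 37.4% had an F-test p under 0.05, 1.1 times the 34% of all genes. That is under the bound set in advance. With 34% of all genes under that p, and the F test also counting differences among treated groups, this could hardly show a segment. Of the 286, 12 were called in a comparison with sham, against 772 of all 33191 genes. That is a larger share, on a measure for which no bound was set. Off-tissue signal as the whole cause is argued against. With its median as a covariate Cd53, well above background on 1 of the 3 sham arrays, was 3.903 higher after POL5551 (SE 0.489), against 5.161 (SE 0.442) before, and both genes passed after 2 and 5 days of G-CSF. The POL5551 calls of both ended (adjusted p = 0.112 and 0.168), as their unadjusted p rose from 1.25e-07 to 1.35e-05 for Cd53 and from 1.14e-06 to 7.54e-05 for Borcs5, and genes at an unadjusted p under 0.05 went from 11631 to 1819. Sham and 2-day arrays had off-tissue medians of -2.784 and -2.572, closer than the SD in sham, 1.025. A response to treatment stays open as a hypothesis, as does any difference in how the shams were handled, which was not tested.

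The stromal and osteoblast list was higher after POL5551 and after 5 days of G-CSF. With an estimated correlation between genes it did not pass in either (adjusted p = 0.269 and 0.593). RNA of stromal cells in the sorted samples may be the source. Deviations of the members from their group means had a mean pairwise correlation of 0.425 over the 12 arrays, against a median of 0.00783 and a 95th percentile of 0.111 in 1000 random lists, and the abundant members Sparc, Col1a2, Cxcl12 and Adipoq were 3.455, 2.783, 3.47 and 3.707 higher after POL5551. Against it, the sort for lineage-negative Kit and Sca-1 positive SLAM cells would remove stromal cells, though its purity was not tested here. Sp7, Kitl and Pdgfra were at -0.413, -0.574 and -0.819 after POL5551. These values lie near the median of all genes in that comparison, so they do not decide the question. Sham 1 alone is argued against, as the means of 1.534 and 1.302 were 1.933 and 1.701 without it. With the off-tissue covariate they were 2.303 and 1.687. The slope of that covariate is fitted within groups and rests largely on sham, whose SD was 1.025, against 0.162 to 0.532 in the other groups. That fit is therefore not fully separate from leaving out sham 1, and off-tissue signal is not excluded. At the preset correlation the highest adjusted p of the list in both comparisons was 2.08e-06 with the covariate and 3.04e-08 without sham 1, while the members go together more than that correlation allows for. With slide as a fixed block, in a fit that rests on 1 array of the 5-day group, the 5-day mean was -0.368. A change in expression by the stem cells was not tested, so neither slide nor treatment is settled for that group.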

How the results depend on the processing

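Alternatives added after the data were seen, so chosen as tests after the result, are the off-tissue covariate, the fit without both sham 1 and 5-day mouse 3, and the block with the mouse numbers of the authors' table. All others were planned. Of the values of single named genes under the alternatives, 8861 kept their direction and side of the threshold, 147 passed anew, 368 no longer passed and 1 reversed. For lists the numbers were 1780 kept, 198 no longer past and 42 reversed. Unless a reason is given, the cause was not tested. Below, normexp means normexp background correction together with quantile normalization, so both choices changed at once.

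With an estimated correlation in camera 0 lists passed in each of the 5 comparisons (3, 0, 2, 1 and 3 at an unadjusted p under 0.05 in the order of the report), while ranks in camera gave 18, 10, 9, 16 and 16.

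For POL5551 against sham, 758 genes became 28 with normexp and quantile normalization, 90 with quantile normalization, 220 with median scaling, 62 with the authors' values, 1897 with only probes above background on all arrays, 63 with only the 2 groups (fewer samples), 401 with array weights, 1926 with the trended and robust prior, 181 with the replicate block, 0 with the off-tissue covariate (1819 at an unadjusted p under 0.05) and 101 without both arrays. With the covariate 8 lists passed, 3 higher and 5 lower, and 2 of them were among the 17 in the same direction. For 2 days of G-CSF, 11 genes became 5 with normexp, 5 with probes above background on all arrays, 0 with only the 2 groups by limma (2096 at an unadjusted p under 0.05), 1137 with array weights, 7 with the trended prior, 6 with the replicate block, 4 with the block of the authors' numbers, 17 with the covariate and 171 without both arrays. Its 9 lists became 14 with array weights, 2 with the covariate and 14 without both arrays. For 5 days of G-CSF, 22 genes became 12 with probes above background on all arrays, 35 with the mean of a gene's probes, 1 with only the 2 groups, 84 with array weights, 0 with slide as a fixed block (2490 at an unadjusted p under 0.05) and 14 with the replicate block, and 8 lists became 15 with the fixed slide block.

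Between the G-CSF courses, 0 genes became 3 with quantile normalization, 7 with only the 2 groups, 12383 with array weights, in which sham 1 had a weight of 0.114, and 241 without both arrays, and 4 lists passed with the covariate, none of them among the 17 in the same direction. For POL5551 against 5 days, 20 genes became 5 with normexp, 5 with probes above background on all arrays, 8 with the authors' values, 60 with only the 2 groups, 251 with array weights, 9 with the trended prior, 0 with the fixed slide block (797 at an unadjusted p under 0.05), 6 with the replicate block, 3 with the block of the authors' numbers and 0 with the covariate (2342 at an unadjusted p under 0.05). Its 15 lists became 5 with the fixed slide block and 0 with the covariate. The F test's 447 genes became 110 with quantile normalization, 215 with median scaling, 3660 with probes above background on all arrays, 73 with the authors' values, 10091 with array weights, 3056 with the trended prior, 23 with the covariate, 9556 without both arrays and 1237 with the block of the authors' numbers. Slide as a fixed block could not be fitted for comparisons with the 2-day group or for the F test.

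For the G-CSF courses r was 0.255 with probes above background on all arrays, 0.268 with array weights and 0.505 with the covariate, and the 6 shared genes became 10 with quantile normalization, 47 with array weights, 12 without both arrays and 2 with the block of the authors' numbers. For POL5551 and 5 days r was 0.644 with array weights, 0.653 without both arrays and 0.818 with the fixed slide block. The 13 shared genes became 2 with normexp, 6 with probes above background on all arrays, 31 with array weights, 8 with the trended prior, 6 with the replicate block, 8 with the block of the authors' numbers, 0 with the covariate, 8 without both arrays and 0 with the fixed slide block. For POL5551 and 2 days r was -0.015 with normexp, -0.118 with probes above background on all arrays, -0.083 with array weights, 0.172 with the covariate and -0.0488 without both arrays. The 4 shared genes became 1 with normexp, 2 with probes above background on all arrays, 2 with the authors' values, 26 with array weights, 2 with the replicate block, 0 with the covariate and 8 without both arrays.

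Leaving out each array in turn gave 60 to 4665 genes for POL5551 against sham, 2 to 166 genes and 0 to 14 lists for 2 days, 1 to 55 genes and 8 to 16 lists for 5 days, 0 to 14 genes between the courses, 0 to 91 for POL5551 against 5 days and 55 to 7671 for the F test. Lists ran from 13 to 18 for POL5551 against sham, 15 to 17 between the courses and 14 to 17 for POL5551 against 5 days. For the courses r ran from 0.312 to 0.598 with 1 to 13 shared genes, for POL5551 and 5 days from 0.559 to 0.829 with 1 to 46, and for POL5551 and 2 days from -0.0488 to 0.349 with 2 to 6. The 5-day means of the unfolded protein list ran from -0.01 to 0.462 and of the glycolysis list from -0.039 to 0.675.

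Single results reversed under few settings. Gdpd2 after POL5551 was at -1.382 with probes above background on all arrays, another probe of the gene having gone the other way. With the off-tissue covariate the tests of these lists turned, means after POL5551 being -0.462 for HSC identity, 0.015 for quiescence, 0.051 for the CXCR4 axis, -0.358 for type I interferon, -0.587 for interferon gamma, -0.252 for the unfolded protein response, -0.251 for MYC, -0.556 for ribosomal proteins, -0.296 for oxidative phosphorylation, -0.23 for glycolysis, -0.396 for cholesterol and -0.211 for megakaryocytes. After 5 days they were -0.07 for S phase, 0.058 for the CXCR4 axis, -0.082 for the unfolded protein response, -0.06 for MYC and -0.143 for glycolysis. Between the courses they were -0.293 for HSC identity, -0.36 for S phase, -0.073 for the CXCR4 axis, -0.15 for STAT targets, -0.195 for type I interferon, -0.301 for interferon gamma, -0.208 for the unfolded protein response, -0.061 for p53, -0.412 for ribosomal proteins, -0.302 for oxidative phosphorylation, -0.308 for glycolysis and -0.162 for cholesterol. For POL5551 against 5 days they were -0.17 for the unfolded protein response, -0.191 for MYC, -0.197 for ribosomal proteins, -0.087 for glycolysis and -0.133 for megakaryocytes. With slide as a fixed block the stromal list after 5 days was at -0.368, and for POL5551 against 5 days the quiescence list was at -0.108, G2/M at -0.205, the unfolded protein response at -0.167, MYC at -0.159 and megakaryocytes at -0.062.

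Mouse numbers of the scanner files showed no clear pairing of the arrays. The 18 pairs with the same number had correlations of deviations from -0.314 to 0.252 (median 0.061). The 36 pairs with different numbers had -0.273 to 0.429 (median -0.008). The difference was not tested, so a weak pairing is not excluded. Signal over background limits genes that are well above background on no array of a group.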

Other observations

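The tests of other splits were planned. The values of marker lists below were computed with the comparisons, and the Selp and Dhrs3 values were chosen after they were seen.

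Splits of the 6 arrays of a pair of groups number 10, too few for a share under 0.05. For POL5551 against sham 1 of the 10 gave as many genes as the real one (758, highest other 64) and 3 as many lists (17, highest other 17). For 2 days of G-CSF it was 1 for genes (11, highest other 10) and 6 for lists (9, highest other 17), and for 5 days 1 for genes (22, highest other 19) and 9 for lists (8, highest other 17). Between 5 and 2 days it was 10 for genes (0 by limma, with 5370 at an unadjusted p under 0.05, highest other 1) and 1 for lists (17, highest other 16). For POL5551 against 5 days it was 1 for genes (20, highest other 0) and 2 for lists (15, highest other 18). In every comparison except 5 against 2 days, another split gave as many lists or more. Those list counts alone therefore do not set the real grouping apart. Over all 12 arrays 100 splits were drawn. For the F test 1 of 100 gave as many genes (447, highest other 96). For genes shared by the G-CSF courses it was 1 (6, highest other 3), for POL5551 and 5 days 1 (13, highest other 12), and for POL5551 and 2 days 3 (4, highest other 36). For these 4 results the share of splits was under 0.05. Such splits mix the arrays of all groups, so they ask only whether the grouping matters at all. For the counts of shared genes they cannot tell a shared response from a difference of the common sham arrays.

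Lists of blood lineages mostly did not pass. After POL5551 the mean log2 difference and adjusted camera p were 0.13 and 0.0909 for primary granule genes, 0.11 and 0.292 for mature neutrophils, -0.20 and 0.703 for macrophages, 0.12 and 0.213 for erythroid genes, -0.42 and 0.703 for B cells, -0.72 and 0.279 for T and NK cells, -0.08 and 0.292 for lymphoid priming, -0.65 and 0.659 for mast cells, -0.56 and 0.696 for dendritic cells and -0.05 and 0.159 for endothelium. The Toll-like receptor list had a mean of -0.09 and an adjusted p of 0.199, its test pointing higher because all genes had a median of -0.52, and the early response list 0.09 and 0.0714. After 2 days of G-CSF the lists that did not pass had adjusted p from 0.0775 (ribosomal proteins) to 0.91 (mature neutrophils), with 0.128 for STAT targets. After 5 days they ran from 0.0570 for oxidative phosphorylation to 0.954. Between POL5551 and 5 days the stromal list had an adjusted p of 0.0586, and 1.06e-10 with slide as a fixed block, where the comparison rests on 1 array of each group. Between the G-CSF courses its mean was 0.50 and its median -0.34 (adjusted p = 0.09).

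Genes outside the naming rule also passed after 5 days of G-CSF. Selp, P-selectin, an adhesion molecule of platelets and endothelium, rose by 2.27 (SE 0.322, adjusted p = 0.0356), and Dhrs3, a retinal reductase, by 2.42 (adjusted p = 0.0484).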
